A study of Mus musculus with 10 samples.

How the data were processed

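Total RNA from forelimb buds of mouse embryos was sequenced in 10 libraries, 5 from control embryos and 5 from embryos with a conditional knockout of Cxxc1. Per the labels, embryos were at embryonic day 11.5 to 12, came from litters named A to D, and the libraries were made with an Illumina RNA library kit. Litter A gave 2 controls and 2 knockouts, and litters B, C and D gave 1 of each. The knockout embryos carried Prx1Cre, a Cre recombinase active in limb bud mesenchyme, and floxed alleles of Cxxc1 on both chromosomes. Control 1 carried Prx1Cre with 1 floxed allele, controls 2, 3 and 4 carried no Cre, and the Cre status of control 5 is marked with a question mark in its label. Groups were taken from the sample titles alone.

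One deposited table held estimated counts per Ensembl mouse gene, which the authors made before deposit. Per the submitters' processing notes, Salmon 0.8.2, R 3.4.1, DESeq2 1.16.1 and the build mm10 were used, with no role given for any of them. How transcripts were summed to genes, and whether reads were assigned by strand, are not given in the sources used here. Of the deposited estimated counts above 0, 0.06% were whole within 1e-06, so all were rounded to whole numbers before any count test. A second deposited table, named as FPKM, held a signal that was not FPKM. Its values were the rounded counts divided by 1 factor per library, since 100.00% of its values above 0 lay within 0.01 of a rounded count after multiplication by that factor. It was used only as an alternative, on a log2 scale with a stated pseudocount. Both tables held 47729 genes, and 0 of their columns belonged to no sample here. Symbols and coordinates came from GENCODE release M21 (GRCm38, the same assembly as mm10), in which 47224 of the gene IDs had a symbol and 505 had none. Genes on the opposite strand share exon bases of Nrarp (79.4%), Gdf5 (40.3%), Ube2c (22.8%), Hand2 (19.6%), Shh (15.7% and 12.7%), Csf1r (15.1%), Fgfr3 (13.9%) and Rspo3 (13.1%), whose counts are less certain if reads were not assigned by strand.

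Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3), knockout against control, with no covariate. P-values were adjusted by Benjamini-Hochberg over the 20562 genes tested, with a threshold of 0.05. Levels are CPM of the TMM-scaled library, computed here from the deposited counts and given as mean ± SD with n = 5 per group. Fold changes are log2 of knockout over control with a standard error (SE). This SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Of 33 gene lists fixed before the data were examined, 32 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the lists. Sex-linked transcripts were given as values. Camera was repeated with an estimated correlation, and fry was run as a test of each list on its own. A list score is the mean log2 CPM of its members minus the control mean. Single values were compared by exact two-sided permutation tests, whose smallest p with 5 against 5 is 0.00794. These permutations ignored the litters. Permuting within litters would allow fewer arrangements and so a larger smallest p.

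Genes named in the text followed a rule set before the data were examined. It took Cxxc1, the 10 largest rises and 10 largest falls, a preset group of limb genes whatever their test, and up to 4 members per list with the smallest adjusted p past the threshold. A gene counted among the 10 largest needed an adjusted p below 0.05, a mean of at least 1 CPM, no overlap between the groups and a standard symbol. Some genes that the rule named are not reported here. The gene families in the closing observations were chosen by name after the data had been seen.

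Totals ran from 33274855 to 49881126 counts per library. A count of 0 allows a level of up to 0.060 CPM in the deepest library and 0.090 CPM in the shallowest, at 3 counts. These limits and all count intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The common dispersion gave a biological coefficient of variation of 16.4%. Pairs of libraries of 1 group differed by a chi-square per degree of freedom of 15.89 to 44.61, so none was a duplicate. Tested on simulated data for this comparison (20562 genes, 50 genes changed at each size), the test recovered 14% of genes changed by 1.25-fold, 50% at 1.5-fold, 64% at 2-fold and 86% at 4-fold. It called 9 unchanged genes, which were 7.76% of its calls. The real comparison called 7245 genes, far more than were changed in the simulation. With so few changed genes the adjustment set a stricter cutoff on the unadjusted p. These shares therefore do not measure recovery at the cutoff of the real data, which is less strict. Camera called the 1 raised list and 0 of 20 lists without a change at a nominal p of 0.05. The simulated genes were drawn independently, whereas the estimated correlation within the fixed lists reached 0.791, for erythroid cells. The simulation therefore does not measure camera's false calls in lists of correlated genes.

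Same-numbered control and knockout embryos were litter-mates per the labels, so the numbers pair the samples by litter. Litter A holds numbers 1 and 2, and within it the labels tie neither control to 1 of the 2 knockouts. Deviations of the 2 members of a pair from their group means correlated at -0.013, 0.155, -0.025, 0.042 and 0.200 for pairs 1 to 5. Fits with the replicate number or the litter as a block were run beside the unpaired one. Other fits run were RLE size factors, library size only, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, somite stage or sex-linked transcript level as a term, controls without Cre only, no litter A, stricter thresholds, the size-factor table and leaving out each library in turn. Leaving out litter D, or the 2 libraries with high Xist, was chosen after the data had been seen. GC content and length came from the longest transcript of each gene.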

Results

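RNA of 10 mouse forelimb buds was compared, 5 from control embryos and 5 from embryos labelled as carrying Prx1Cre, active in limb bud mesenchyme, and floxed Cxxc1 on both alleles. CXXC1 is a protein that binds unmethylated CpG and belongs to the SET1 complexes, which methylate histone H3 at lysine 4. The series title names BMP signaling and progenitor differentiation as the question. Somite stage was 50.2 ± 0.84 (SD, n = 5) in controls and 50.0 ± 1.00 (SD, n = 5) in knockouts. Controls had total counts of 45971139, 44170158, 49001179, 48946712 and 46235789, and knockouts of 38896281, 49881126, 33274855, 43084835 and 47907585. Nothing in the labels gives the sex of the embryos. Xist, the transcript of the inactive X chromosome, was at 4114 CPM in control 1 and 2290 CPM in knockout 3, and between 0.360 and 5.48 CPM in the other 8 libraries.

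Cxxc1 (ENSMUSG00000024560, chromosome 18, 74216124 to 74221496, plus strand, GRCm38) was lower in every knockout library than in every control. It was at 96.7 ± 6.88 CPM in controls and 75.2 ± 1.23 CPM in knockouts (SD, n = 5 each). The control libraries held 91.4, 95.4, 105.8, 101.6 and 89.5 CPM, and the knockout libraries 75.1, 75.8, 76.2, 75.8 and 73.1 CPM. Its log2 fold change was -0.36 (SE 0.05, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.000144), and the exact two-sided permutation p of the CPM was 0.00794, the smallest 5 against 5 can give. The count covers the whole gene and does not resolve the deleted part, which is not given in the sources used here, and the buds also hold cells outside the reach of Prx1Cre.

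In the knockout, genes of cartilage, tendon and connective tissue fell, p53 target genes and macrophage genes rose, and BMP pathway genes moved in both directions. Camera called the lists of cartilage, tendon, p53 and macrophage genes, but not with an estimated correlation (adjusted p = 0.143 for chondrogenesis, tendon and connective tissue, and macrophages, and 0.0692 for p53 targets). Of 20562 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3719 higher and 3526 lower, 35.2% in all. At least 2-fold changes were found for 988 genes called higher and 460 called lower. In 5211 genes (25.3%) the 2 groups did not overlap, where chance gives 0.79%. Of the 7245 called genes, 6759 (93.3%) moved in the called direction in all 4 litters, which the calls on these same libraries in part ensure. Of the genes not called, 21.5% had 1 direction in all 4 litters, where chance gives 12.5%. The called genes were 51.3% higher with TMM and 62.2% higher when scaled by library size only, with a median log2 fold change over all genes of -0.001 and 0.051. Without litter A, 3 against 3, 2002 genes were higher and 2021 lower. The first principal component held 44.4% of the variance and the second 10.8%.

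Of the 32 lists tested with camera, 10 were higher and 7 lower at an adjusted p below 0.05. With an estimated correlation camera called 0 lists after adjustment and 6 at an unadjusted p below 0.05, and fry called 22. The smallest adjusted p with an estimated correlation was 0.0692, for the p53 targets.

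**Figure D1:**
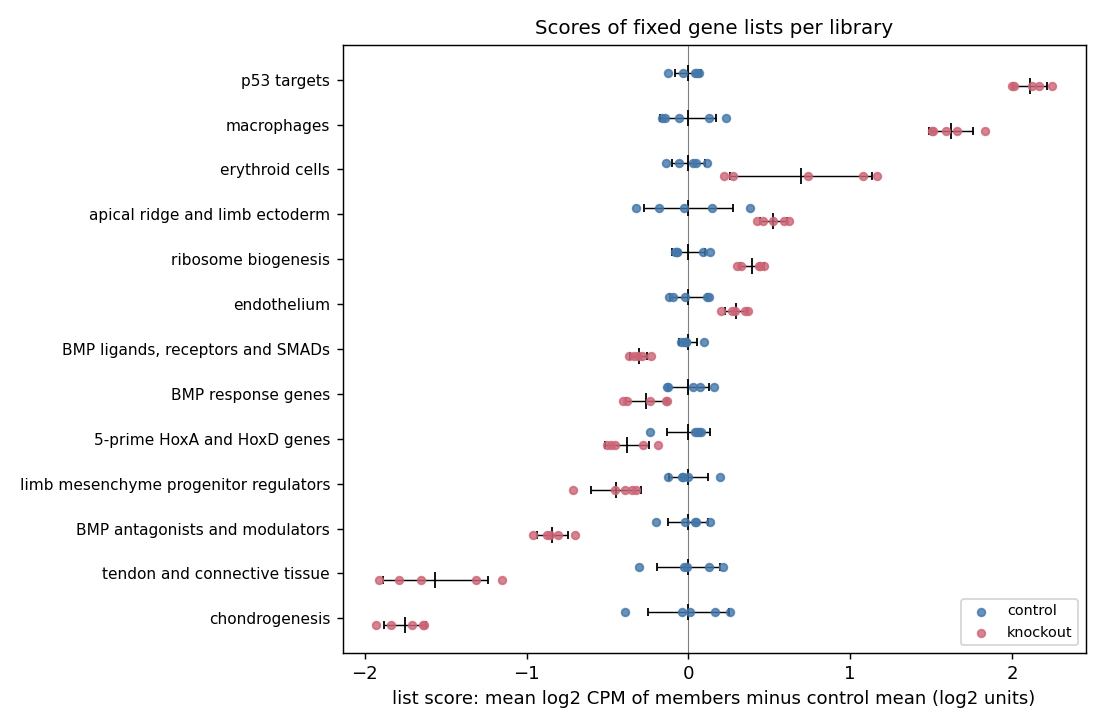
Score of 13 of the fixed gene lists in each library, on the horizontal axis as mean log2 CPM of the members minus the control mean, with controls in blue and Cxxc1 knockouts in red (n = 5 each). Black marks give the group mean and its SD. The p53 target score lay between 2.0 and 2.25 in the knockouts and the chondrogenesis score between -1.93 and -1.63, with no overlap with the controls in either.

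Cartilage genes fell. Sox9, the transcription factor that starts cartilage formation (chromosome 11, 112782224 to 112787760), was at 115.9 ± 29.6 CPM in controls and 19.3 ± 3.65 CPM in knockouts (SD, n = 5 each), a log2 fold change of -2.59 (SE 0.18). Col2a1, the main collagen of cartilage (chromosome 15, 97975602 to 98004695), was at 396 ± 80.3 and 93.4 ± 10.8 CPM, and the aggrecan gene Acan at 6.71 ± 1.55 and 0.431 ± 0.0464 CPM. Of 30 measured chondrogenesis genes, 22 fell, 0 rose and 8 did not pass edgeR's test at a Benjamini-Hochberg adjusted p of 0.05, with the same 22 and 0 adjusted over the list alone. Further examples are Wwp2 (-1.40, SE 0.08) and Col9a2 (-3.05, SE 0.20). The mean log2 fold change of the list was -1.87, and camera gave an adjusted p of 9.1e-12 (adjusted p = 0.143 with an estimated correlation). On the score scale the change was -1.75, and from -2.09 to -1.25 within the 4 litters. In Nkx3-2, a transcription factor of early cartilage, the controls held 620 counts in all and the knockouts 1, a ratio of 585 with a 95% counting interval of 105 to 23100. That count was in knockout 4, without which the fitted log2 fold change moved from -8.53 to -9.93. Control 4 was at 0.334 CPM and the other controls between 2.79 and 4.25 CPM, a spread that the counting interval does not cover. With Nkx3-2 at the near end of that interval the mean of the list was -1.81 and its median -1.40. In the same libraries the markers of macrophages, limb ectoderm, endothelium and erythroid cells were higher (mean log2 fold changes 1.63, 0.51, 0.29 and 0.75).

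Genes of tendon and loose connective tissue fell as well. Of 15 measured, 12 fell, 0 rose and 3 did not pass, and 15 fell when adjusted over the list alone. Examples are the transcription factors Osr2 (25.7 ± 4.07 CPM in controls, 5.95 ± 1.08 in knockouts) and Ebf1 (88.1 ± 28.7 and 12.6 ± 4.31 CPM) and the keratocan gene Kera (21.9 ± 1.57 and 2.52 ± 1.37 CPM). The mean log2 fold change was -1.52, and camera gave an adjusted p of 4.3e-08 (adjusted p = 0.143 with an estimated correlation). Of 13 osteogenic and perichondrial genes, 2 rose, 4 fell and 7 did not pass, with the same counts adjusted over the list alone. Col1a1 was -1.40 (SE 0.17), Bmp3 -2.87 (SE 0.19) and Alpl, an alkaline phosphatase of bone precursors, +1.33 (SE 0.19). Runx2, the transcription factor that starts bone formation, was at 9.87 ± 3.24 and 12.8 ± 3.32 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.262). Camera did not call this list (mean -0.36, adjusted p = 0.276).

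**Figure D2:**
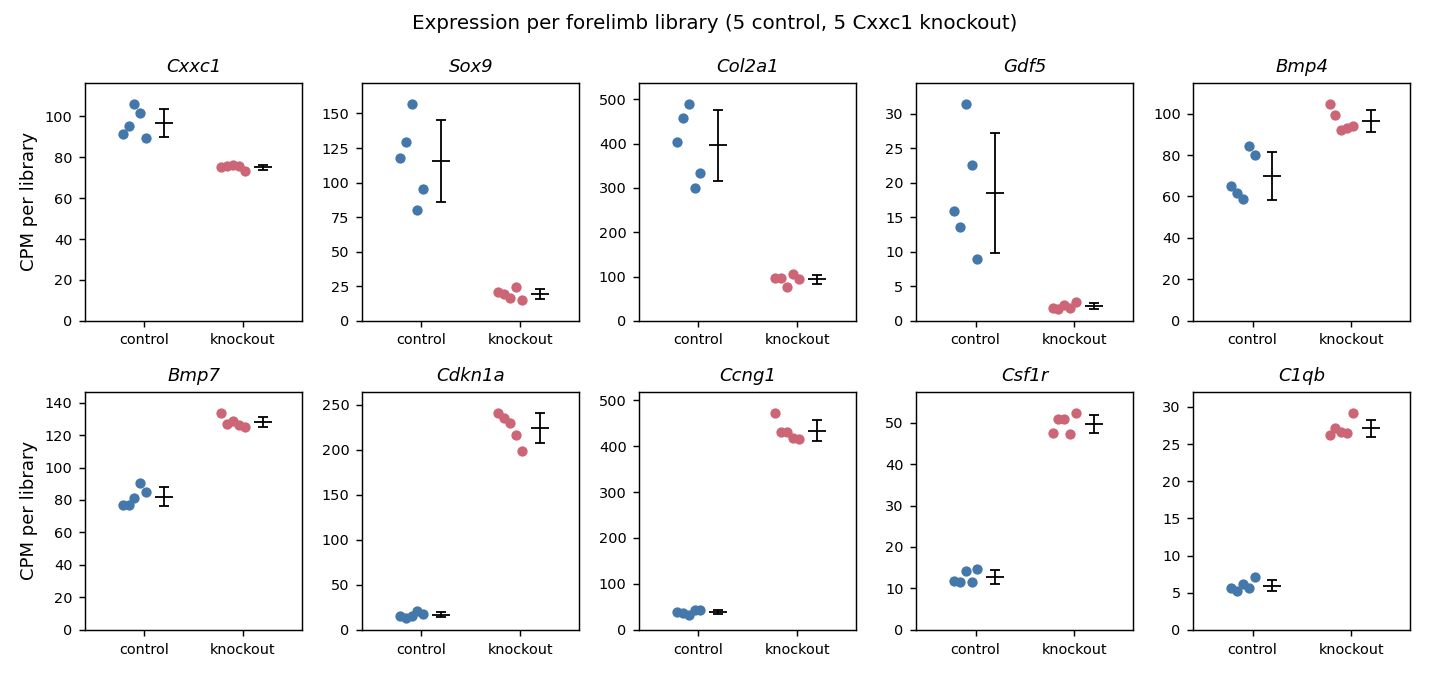
Expression of 10 genes in each library, with CPM on the vertical axis from 0, controls in blue and Cxxc1 knockouts in red; black marks beside the points give the mean and SD (n = 5 each). Sox9, Col2a1 and Gdf5 lay lower, and Bmp4, Bmp7, Cdkn1a, Ccng1, Csf1r and C1qb higher, in every knockout library than in every control; Cxxc1 fell from a mean of 96.7 to 75.2 CPM.

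BMP pathway genes moved in both directions. Among the ligands, Bmp7 rose from 82.0 ± 5.88 to 128.0 ± 3.22 CPM (log2 fold change 0.64, SE 0.05) and Bmp4 from 70.0 to 96.6 CPM (0.46, SE 0.10). Gdf5, a ligand of forming joints (chromosome 2, 155941023 to 155945367), fell from 18.5 ± 8.71 to 2.12 ± 0.435 CPM (-3.12, SE 0.31). Bmp2 was at 30.1 ± 3.12 and 26.3 ± 4.53 CPM and did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.213). The receptor genes Bmpr1a and Bmpr1b fell by 0.41 (SE 0.06) and by 0.88 (SE 0.17) on the log2 scale, and Smad5, a transducer of the pathway, fell by 0.24 (SE 0.04). Of 17 measured ligands, receptors and SMADs, 2 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone. Camera did not call the list (mean -0.32, adjusted p = 0.0719, and 0.292 with an estimated correlation), although its score lay lower in all 4 litters (-0.43 to -0.21). Fry, which tests each list on its own, gave it an adjusted p of 0.00249, and 22 of the 32 lists passed fry. The list passed camera without the filter on low counts (mean -0.32, adjusted p = 0.0246). Without litter A, 3 against 3, the list passed (mean -0.34, adjusted p = 0.032), Bmp2 passed (-0.45, adjusted p = 0.0183), and Bmp4 (0.32, adjusted p = 0.108) and Bmpr1b (-0.58, adjusted p = 0.0822) did not. A gene on the opposite strand shares 40.3% of the exon bases of Gdf5, and counts without strand cannot separate the 2.

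Among 18 genes known to respond to BMP, 5 fell, 1 rose and 12 did not pass, with the same counts adjusted over the list alone. Id1, a direct target of BMP SMADs, fell from 146.6 ± 7.60 to 99.8 ± 13 CPM (-0.55, SE 0.08). Id4 (-1.10, SE 0.15) and Hand1 (-2.72, SE 0.61) fell too, and Hand1 was at -3.36 without knockout 1. Gata2 was the gene that rose (0.82, SE 0.24), and its call was lost without litter A (0.39), with controls without Cre only (0.72) and without the 2 libraries with high Xist (0.67). Id3 (-0.11), Msx1 (0.27) and Msx2 (0.22) did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.380, 0.152 and 0.243). Without control 4, Msx1 passed (0.38, adjusted p = 0.0276). Camera did not call the list (mean -0.24, adjusted p = 0.271, and 0.630 with an estimated correlation). Its score changed by -0.01 in litter A and between -0.45 and -0.40 in litters B, C and D, and without litter A it passed (mean -0.41, adjusted p = 0.019), as did Id3 (-0.29, adjusted p = 0.0279).

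The BMP antagonists and modulators fell as a list. Bmper was at 9.16 ± 1.27 and 1.13 ± 0.250 CPM, Nbl1 at 63.5 ± 9.71 and 9.50 ± 2.90 CPM and Chrdl1 at 26.0 ± 8.56 and 3.94 ± 1.23 CPM, and the chordin gene Chrd fell by 0.97 on the log2 scale (SE 0.13). Grem1, the antagonist of the distal bud, was at 50.1 ± 8.70 and 55.7 ± 6.12 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.341). Of 13 measured, 7 fell, 0 rose and 6 did not pass, and 8 fell when adjusted over the list alone. The mean was -0.84, and camera gave an adjusted p of 0.00328 (adjusted p = 0.254 with an estimated correlation).

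Regulators of limb mesenchyme progenitors split. Pdgfra, a receptor of mesenchymal cells (chromosome 5, 75152292 to 75198215), fell from 492.6 ± 45.4 to 135.1 ± 5.27 CPM (-1.87, SE 0.07), and Prrx1, whose enhancer drives the Cre, fell from 578.1 ± 25.6 to 297.1 ± 15.9 CPM (-0.96, SE 0.05). Tbx5, which starts forelimb outgrowth, fell by 1.09 (SE 0.09) and Pax9 by 3.13 (SE 0.23) on the log2 scale. Fgf10 was at 30.6 ± 3.01 and 30.9 ± 4.89 CPM, and Hand2 at 173.4 ± 15.9 and 149.6 ± 16.3 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.939 and 0.0569). Hand2 passed at log2 fold changes of -0.25, -0.25 and -0.26 without control 3, knockout 1 or knockout 2, and at -0.35 without litter A. With all 10 libraries it passed with DESeq2 (-0.21, adjusted p = 0.0489) and with somite stage as a term in edgeR (-0.22, adjusted p = 0.0467). Of 23 measured, 3 rose, 10 fell and 10 did not pass, and adjusted over the list alone 11 fell and 3 rose. The mean was -0.45, and camera gave an adjusted p of 0.00194 (adjusted p = 0.143 with an estimated correlation). Of 11 genes of the 5' HoxA and HoxD clusters, 7 fell and 4 did not pass, with the same counts adjusted over the list alone (mean -0.38, camera adjusted p = 0.00328, adjusted p = 0.381 with an estimated correlation). Hoxd12 fell by 1.06 (SE 0.13) and Hoxd9 by 0.64 (SE 0.07), while Hoxa13 (-0.07) and Hoxd13 (-0.10) did not pass. Hoxa13 passed without litter A (-0.32, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0376).

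Genes of the limb ectoderm and apical ridge were higher as a list, and Shh rose. Fgf8, a growth factor of the apical ridge, was at 12.3 ± 4.59 and 25.8 ± 2.44 CPM (1.07, SE 0.21), and Shh, the signal of the posterior margin, at 3.75 ± 1.73 and 8.74 ± 1.35 CPM (1.22, SE 0.29). Of 23 ectoderm and ridge genes, 16 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone. Krt5 rose by 0.86 (SE 0.11) and Sp8 by 1.03 (SE 0.14). The mean was 0.51, with a change on the score scale from 0.08 in litter C to 0.77 in litter B, and camera gave an adjusted p of 1.4e-05 (adjusted p = 0.381 with an estimated correlation). Of 15 genes of FGF response and feedback, 10 rose, 3 fell and 2 did not pass, with the same counts adjusted over the list alone. Etv4 (1.31, SE 0.10), Dusp6 (0.53, SE 0.07) and Il17rd (0.35, SE 0.05), which are induced by FGF signals, rose, and the receptor Fgfr3 fell by 1.05 (SE 0.15). Camera called this list (mean 0.23, adjusted p = 0.0378, adjusted p = 0.397 with an estimated correlation), but not with a replicate block of number or litter (adjusted p = 0.0813 and 0.0681). Its call was also lost without control 1, 2 or 3 (means 0.22, 0.21 and 0.23), without knockout 1 or 2 (0.21 and 0.23), without litter A (0.14), with controls without Cre only (0.21) and without the 2 libraries with high Xist (0.22).

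The hedgehog list had no common direction. The targets Gli1 (0.53, SE 0.08) and Ptch1 (0.37, SE 0.08) rose, and the co-receptor Boc fell by 1.06 (SE 0.14). In all, 5 of 12 rose, 6 fell and 1 did not pass, and 5 rose and 7 fell when adjusted over the list alone. The mean was 0.04, the median -0.19 and camera's direction lower (adjusted p = 0.733). Without litter A, Shh (1.21, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.092), Ptch1 (0.27, 0.125) and Fgf8 (0.82, 0.0502) no longer passed. Of 22 WNT genes, 7 rose, 8 fell and 7 did not pass, with 7 and 9 adjusted over the list alone (mean -0.15, median 0.05, camera adjusted p = 0.609). The ligand Wnt11 fell by 2.58 (SE 0.21) and the secreted factor Rspo3 by 1.89 (SE 0.11), and the WNT target Sp5 rose by 2.38 (SE 0.17). Of 13 genes of retinoic acid, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. The enzymes Aldh1a2, which makes retinoic acid, and Cyp26b1, which degrades it, fell by 1.95 (SE 0.23) and by 1.21 (SE 0.09). Camera called this list (mean -0.36, adjusted p = 0.0286, adjusted p = 0.292 with an estimated correlation), but not without control 5 (-0.31), knockout 2 (-0.34), litter A (-0.37) or litter D (-0.33), nor with controls without Cre only (-0.32). Of 12 Notch genes, 6 rose, 2 fell and 4 did not pass, and 8 rose and 2 fell adjusted over the list alone (mean 0.18, camera adjusted p = 0.147). Jag2 rose by 0.70 (SE 0.11) and Notch2 fell by 0.44 (SE 0.07).

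Targets of p53, which arrest the cell cycle or promote cell death, rose. Cdkn1a, an inhibitor of cyclin-dependent kinases (chromosome 17, 29090976 to 29100727), was at 16.8 ± 2.79 CPM in controls and 224.0 ± 16.6 CPM in knockouts (3.74, SE 0.11). Ccng1 (chromosome 11, 40748552 to 40755311) was at 39.1 ± 4.77 and 433.5 ± 22.4 CPM, Sesn2 at 17.0 ± 1.03 and 134.1 ± 12.6 CPM and Zmat3 at 37.0 ± 1.08 and 150.4 ± 11.3 CPM. Of 20 measured targets, 19 rose, 0 fell and 1 did not pass edgeR's test at a Benjamini-Hochberg adjusted p of 0.05, and 20 rose when adjusted over the list alone. The mean was 2.19, between 1.93 and 2.25 within the 4 litters on the score scale, and camera gave an adjusted p of 8.4e-23 (adjusted p = 0.0692 with an estimated correlation). Control 1, which carried Prx1Cre with 1 floxed allele, had a p53 score of 0.05, within the range of the other controls (-0.13 to 0.07).

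Of 18 G2/M genes, 10 fell, 0 rose and 8 did not pass, with the same counts adjusted over the list alone. Ube2c fell by 0.45 (SE 0.04), Ccnb2 by 0.41 (SE 0.04) and Top2a by 0.35 (SE 0.05). The mean was -0.20, and camera gave an adjusted p of 0.000347 (adjusted p = 0.292 with an estimated correlation). Of 20 G1/S and replication genes, 2 rose, 3 fell and 15 did not pass, with the same counts adjusted over the list alone (mean -0.05, camera adjusted p = 0.482).

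Markers of macrophages rose together. Csf1r, the receptor that macrophages need (chromosome 18, 61100598 to 61132149), was at 12.8 ± 1.63 CPM in controls and 49.7 ± 2.22 CPM in knockouts (1.96, SE 0.08), C1qb at 5.93 ± 0.719 and 27.1 ± 1.2 CPM and Adgre1 at 2.84 ± 0.353 and 17.7 ± 1.60 CPM. Of 15 measured, 14 rose, 0 fell and 1 did not pass, with the same counts adjusted over the list alone. The mean was 1.63, and camera gave an adjusted p of 3.2e-14 (adjusted p = 0.143 with an estimated correlation). Of 13 erythroid genes, 11 rose and 2 did not pass, and 13 rose adjusted over the list alone (mean 0.75, camera adjusted p = 0.000347, adjusted p = 0.397 with an estimated correlation). Within litters the erythroid score rose by 0.10 in litter D and 0.71 to 1.11 in the others, and near-identical globin copies cannot be told apart with certainty. Of 16 endothelial genes, 9 rose and 7 did not pass, and 10 rose adjusted over the list alone (mean 0.29, camera adjusted p = 0.000943, adjusted p = 0.317 with an estimated correlation), Egfl7 by 0.42 (SE 0.07).

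Camera did not call the list of myogenic cells, and 6 of its 19 members rose. Pax3 rose from 3.81 ± 0.773 to 15.9 ± 4.32 CPM (2.06, SE 0.21) and Lbx1 from 9.30 ± 1.7 to 24.9 ± 5.46 CPM (1.42, SE 0.17), both transcription factors of these precursors. None of the 19 fell and 13 did not pass, with the same counts adjusted over the list alone (mean 0.14, camera adjusted p = 0.550). The mean was 0.33 without knockout 1, 0.02 without knockout 4 and 0.01 without knockout 5. The list score was -1.15 in knockout 1 and between 0.02 and 0.54 in the other knockouts. Of 16 Schwann, nerve and melanoblast genes, 2 rose, 4 fell and 10 did not pass, with the same counts adjusted over the list alone (mean -0.19, camera adjusted p = 0.326), and Sox10 fell by 0.84 (SE 0.20). Of 11 genes of trunk tissue, 2 rose and 9 did not pass, with 0 and 0 adjusted over the list alone (mean 0.61, camera adjusted p = 0.578). The mean was 0.97 without control 5 and -0.01 without the 2 libraries with high Xist. These were Afp (5.51, SE 1.61), a protein of fetal liver and yolk sac, and Foxf1 (1.12, SE 0.38). Afp overlapped between the groups, from 0.0191 to 97.1 CPM in knockouts, and its log2 fold change was 7.40 without control 5 and 4.62 without knockout 5. Its call was lost with limma-voom (3.71) and with the size-factor table (3.70 to 3.83). The Foxf1 call was lost without control 1, 3, 4 or 5 (1.02, 1.15, 1.18 and 0.97) and without knockout 1, 2 or 4 (0.96, 0.88 and 1.14).

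Of 18 genes of the CXXC1, SET1 and MLL complexes, 3 rose, 4 fell and 11 did not pass, with the same counts adjusted over the list alone (mean -0.05, camera adjusted p = 0.609), and Wdr5 rose by 0.22 (SE 0.04). Of 13 genes of DNA methylation, 2 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone (mean 0.22, median -0.02, camera's direction lower, adjusted p = 0.733). Dnmt3a fell from 442.6 ± 22.6 to 307.4 ± 17.7 CPM, and Dnmt3l, at 0.0339 ± 0.0351 CPM in controls, was at 0.533 ± 0.192 CPM in knockouts (3.83, SE 0.55, and 4.43 without control 4). Of 20 germline genes silenced by DNA methylation, 5 were measured, and 1, Brdt, fell (-0.98, SE 0.18), while the list mean was 0.05 with camera's direction lower (adjusted p = 0.983), 1 of them also past the threshold adjusted over the list alone.

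Genes of ribosome biogenesis rose, 15 of 20 with 5 not passing, and 16 adjusted over the list alone (mean 0.39, camera adjusted p = 2.4e-06, adjusted p = 0.317 with an estimated correlation). Utp20 rose by 0.64 (SE 0.05) and Ddx21 by 0.51 (SE 0.06). Of 13 mitochondrially encoded transcripts, 7 rose and 6 did not pass, and 9 rose adjusted over the list alone (mean 0.36, camera adjusted p = 0.00537, adjusted p = 0.490 with an estimated correlation). These transcripts made up 1.79% to 2.36% of counts in controls and 2.29% to 3.13% in knockouts. Of 14 interferon response genes, 7 rose, 1 fell and 6 did not pass, and 8 rose and 1 fell adjusted over the list alone (mean 0.68, camera adjusted p = 0.0181, adjusted p = 0.143 with an estimated correlation). Ifitm3 rose by 1.61 (SE 0.10) and Bst2 by 1.68 (SE 0.11), and with a filter of 1 CPM in 5 libraries the list did not pass (0.53, adjusted p = 0.191). Of 14 immediate early and handling stress genes, 7 rose, 2 fell and 5 did not pass, and 8 rose and 3 fell adjusted over the list alone (mean 0.57, camera adjusted p = 0.0286, adjusted p = 0.365 with an estimated correlation). Egr1 rose by 2.06 (SE 0.24), and the list did not pass without control 4 (0.54), knockout 1 (0.49), knockout 4 (0.50) or knockout 5 (0.47). Of 18 genes of glycolysis and hypoxia, 2 rose, 3 fell and 13 did not pass, with 1 and 3 adjusted over the list alone (mean -0.05, camera adjusted p = 0.609), Ddit4 by 0.82 (SE 0.07) among those that rose and Vegfa by -0.57 (SE 0.06) among those that fell. Of 18 genes of the integrated stress response, 4 rose, 4 fell and 10 did not pass, and 4 rose and 5 fell adjusted over the list alone (mean -0.00, median 0.02, camera's direction lower, adjusted p = 0.859).

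Among all genes tested, the 10 largest rises by the naming rule ran from a log2 fold change of 4.55 to 6.33 and the 10 largest falls from -8.53 to -3.57, where -8.53 is the fitted value of Nkx3-2 and no bound. Ano3, a membrane protein of the anoctamin family, was at 0.314 ± 0.176 CPM in controls and 25.7 ± 4.40 CPM in knockouts (SD, n = 5 each), Ptprv at 1.72 ± 0.901 and 86.4 ± 10.3 CPM and the p53 target Eda2r at 1.68 ± 0.521 and 61.5 ± 4.26 CPM. The other rises were Sec14l5, Slc13a3, Dglucy, Klhdc7a, Hmcn2, Svop and Wnt8a. Without control 5 the log2 fold change of Slc13a3 moved from 5.55 to 6.84, and without control 4 that of Hmcn2 from 4.71 to 6.21. Matn4, a matrilin of cartilage, was at 15.5 ± 6.52 and 0.383 ± 0.205 CPM, Cnmd, which encodes chondromodulin, at 7.31 ± 2.81 and 0.182 ± 0.171 CPM and Tbx22 at 2.60 ± 1.33 and 0.0847 ± 0.0472 CPM. The other falls were Nkx3-2, Gng4, Rflna, Kcnd3, Acan, Cntnap3 and Pamr1. Kcnd3 was at -4.17 and at -3.55 without control 2, and its call was lost without litter A (-3.51) and with limma-voom (-3.13).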

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

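The tests of cell share, blood, Cre and somite stage in this part were chosen after the results had been seen. The tests of GC content and length and of other splits of the samples were chosen before.

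Macrophage markers rose in the knockout by a mean log2 fold change of 1.63. A lower share of mesenchyme as the whole cause would raise markers of every other cell type alike. The macrophage score rose over the endothelial score by 1.33 (exact permutation p = 0.00794, the smallest 5 against 5 can give). The list means were known when endothelium was chosen. They were 0.29 for endothelium, 0.51 for ectoderm, 0.75 for erythroid cells, 0.14 for myogenic cells and -0.19 for Schwann, nerve and melanoblast genes. A lower share as part of the rise stays open. Blood carried into the sample as the whole cause would raise erythroid genes alike, and the macrophage score rose over the erythroid score by 0.93 (exact permutation p = 0.00794). Another hypothesis left open is that more macrophages, or more active ones, may be present in the knockout bud, which bulk RNA cannot separate.

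Targets of p53 rose by a mean of 2.19. Removing each library's GC and length trend in the replicate-block fit left the list mean at 2.07, against 2.11 before, while 3557 genes moved by more than 0.1. The median absolute change by the correction was 0.059, small beside the mean of these targets. That Cre alone may raise these genes stays open. Control 1, the 1 library labelled with Cre and 1 floxed allele, lay 0.07 above the mean of the other controls, whose highest lay 0.08 above it, against a knockout rise of 2.12. With 1 such library, Cre and the loss of Cxxc1 cannot be told apart by these data.

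Chondrogenic genes fell by a mean of 1.87 on the log2 scale. A lower share of mesenchyme as the whole cause would lower progenitor genes alike. The progenitor score fell less than the chondrogenic score, a difference of 1.30 (exact permutation p = 0.00794). Both changes were known when this test was chosen. Of 23 progenitor genes 10 fell, among them Pdgfra (-1.87) and Prrx1 (-0.96), and 3 rose. A lower share as part of the cause stays open. The 3 knockouts of at least 50 somites had a chondrogenic score 1.64 below that of the 3 controls of at most 50 (a difference of -1.64, SDs 0.17 and 0.28, no overlap, against -1.75 over all libraries), which argues against a lower somite stage as the whole cause. After removing GC and length trends in the replicate-block fit the list mean was -1.78, against -1.75 before. This correction, with a median absolute change over genes of 0.059, was small beside the list mean. A loss of chondrogenic differentiation with Cxxc1 is a hypothesis in line with these tests, and a loss of chondrogenic cells alone was not tested and stays open.

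Grouping by chance was tested with 100 splits of the 10 libraries into 5 and 5, and 1 of them, the real one, called as many genes. It called 7245, the highest of the others called 1, and the 12 other splits drawn that part all 5 pairs called at most 1. All the other splits, those 12 included, mix knockouts and controls on both sides, which widens the spread within each side. Few calls were therefore to be foreseen in them, and the splits cannot show how many genes chance alone would call.

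Of 312 sets of 5 values (1 gene in 1 group), 26 held a library far from the other 4, where chance gives about 1 in 20. Control 4 held 7 of these, control 3 held 5, knockout 1 held 4, control 5 and knockout 4 held 3 each, knockout 5 held 2, and knockouts 2 and 3 held 1 each. In control 4, Hmcn2 was at 1.34 CPM, Etv4 at 69.3, Nrarp (79.4% of its exon bases shared with a gene on the opposite strand) at 43.3, Dut at 136 and Psat1 at 148 CPM, above the other controls, and Pdgfra at 413 and Dhrs3 at 14.8 CPM, below them. In control 3, Id4 was at 7.76 CPM, Dll4 at 9.19, Ecscr at 8.5, Tek at 23.5 and Vegfa at 84.4 CPM, above the other controls. In control 5, Slc13a3 was at 0.247 CPM, Myf5 at 4.41 and Afp at 2.99 CPM, above the other controls. In knockout 1, Dusp6 was at 232 CPM and Cyp26b1 at 145 CPM, above the other knockouts, and Met at 49.9 and Lbx1 at 15.2 CPM, below them. In knockout 4, Nkx3-2 was at 0.023 CPM, from 1 count where the other knockouts had 0, and Brdt at 2.46 CPM was above the others and Rflna at 0.161 CPM below them. In knockout 5, Adgre1 was at 20.4 CPM and Oas1a at 1.27 CPM, above the other knockouts. In knockout 2, Pdgfra was at 126 CPM, and in knockout 3, Pfkp was at 5.52 CPM, both below the other knockouts.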

How the results depend on the processing

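Leaving out litter D, or the 2 libraries with high Xist, was chosen after the data had been seen. Over all settings, 4118 of 4201 values of 156 named genes kept their direction and their side of the threshold, 64 lost the call, 10 gained one and 9 reversed; of 896 values of 32 lists, 836 kept both, 37 lost the call, 6 gained one and 17 reversed. Apart from Cxxc1 and the preset limb genes, the named genes were chosen by adjusted p or size of change in these same libraries. That choice in part ensures that they keep their calls, so the share does not hold for all genes. Cxxc1 kept its call in each fit it was tested in. Stricter thresholds were applied to gene counts alone. Gene counts moved beyond 1.5 times without litter A (2002 higher, 2021 lower, from fewer samples), at an adjusted p below 0.01 (2431, 2307) and at a log2 fold change of at least 1 (988, 460). Leaving out each library gave 3183 to 3600 higher and 3096 to 3428 lower. With the replicate block of number 3491 were higher and 3359 lower, with that of litter 3723 and 3591, and 16 lists passed with each; the paired fits changed the call of the FGF list and no other. With an estimated correlation 0 lists passed, at unmoved means: BMP antagonists -0.84, progenitor regulators -0.45, chondrogenesis -1.87, tendon -1.52, ectoderm 0.51, erythroid cells 0.75, macrophages 1.63, G2/M -0.20, p53 targets 2.19 and ribosome biogenesis 0.39. BMP ligands, receptors and SMADs passed without a filter (-0.32), without litter A (-0.34) and with the size-factor table at pseudocounts of 1 (-0.30), 0.1 (-0.30) and 1 with no filter (-0.30), and BMP response genes without litter A (-0.41); the cause was not tested. Reversed values, of which trunk tissue started at 0.61, Msx1 at 0.27 and DNA methylation and Msx2 at 0.22, were these: with library size only, G1/S 0.0053, CXXC1 complexes 0.0023, glycolysis 0.0049 and integrated stress response 0.0478; with a filter of 1 CPM in 5 libraries, which tests fewer genes, DNA methylation -0.0753, germline genes -0.0650 and integrated stress response 0.0727; with the litter block, germline genes -0.0013; with controls without Cre, integrated stress response 0.0128 and Fgf10 -0.0323; with limma-voom, Fgf10 -0.0014; without litter A, integrated stress response 0.0091, Msx1 -0.0411, Msx2 -0.113 and Fgf10 -0.0940; without the libraries with high Xist, hedgehog -0.0001 and trunk tissue -0.0070; without litter D, integrated stress response 0.0038. Leaving out 1 library, Fgf10 ran from -0.0791 to 0.0653, integrated stress response from -0.0206 to 0.0330 and germline genes from -0.0439 to 0.10; the cause was not tested. Depth limits genes near 0.060 to 0.090 CPM.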

Other observations

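The gene families in this part, and the members named, were chosen after the data had been seen, and so was the test of muscle precursors; the test of CpG was chosen before its result was seen.

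Of 26 imprinted genes measured, 11 fell, 3 rose and 12 did not pass edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Igf2, a fetal growth factor, was at 3400 CPM in controls and 1840 CPM in knockouts, H19 at 5270 and 2860, Cdkn1c at 521 and 276 and Dlk1 at 66.8 and 26.0 CPM, while Phlda2 was at 2.10 and 5.07 CPM. Camera gave this family an adjusted p of 0.0178 (mean log2 fold change -0.22, adjusted p = 0.526 with an estimated correlation). Of 44 collagens, 22 fell and 9 rose (mean -0.61, adjusted p = 0.00106, and 0.427 with an estimated correlation), of 21 ephrins and Eph receptors 10 fell and 3 rose (mean -0.26, adjusted p = 0.0102, and 0.281 with an estimated correlation), and of 9 T-box genes 5 fell and 0 rose (mean -0.93, adjusted p = 0.0178, and 0.196 with an estimated correlation). The median of the T-box genes was -0.46, and Tbx22, among the 10 largest falls above, was at -4.86. Tbx5 and the collagens Col2a1, Col9a2, Col1a1 and Col1a2 also belong to lists tested above, so these families are not separate from them. Tbx18 was at 133 and 40.6 CPM.

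Of 80 cytosolic ribosomal protein genes, 37 fell and 5 rose (mean -0.15, camera adjusted p = 4.5e-06, and 0.526 with an estimated correlation). By contrast, 15 of 20 genes of ribosome biogenesis rose and 5 did not pass (mean 0.39, camera adjusted p = 2.4e-06, and 0.317 with an estimated correlation). Of 50 replication-dependent histone genes, 12 fell and 0 rose (mean -0.61, adjusted p = 3.8e-06, and 0.0853 with an estimated correlation), most of them at a few CPM or less. Of 27 lysosomal genes, 14 rose and 2 fell (mean 0.30, adjusted p = 0.00106, and 0.427 with an estimated correlation), with Ctsb at 136 and 259 CPM. The largest rises of the family were Ctsh (1.36) and Ctsk (1.33), and macrophage markers rose by a mean of 1.63 in the same libraries. Of 22 gamma protocadherins, whose transcripts share exons, 5 fell and 2 rose (mean -0.15, adjusted p = 0.0498, and 0.526 with an estimated correlation). Fibroblast growth factors (adjusted p = 0.975), WNT ligands (0.934), semaphorins and plexins (0.578), Irx (0.975), Fox (0.662), Sox (0.272), MHC class I (0.272) and solute carrier genes (0.434) did not pass. These directions were the same with RLE factors and with library size only.

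CXXC1 binds unmethylated CpG, so its loss may lower genes with CpG-rich 5' ends more often than others. Among called genes, the odds of being lower rather than higher were 1.11 times as high for the CpG-rich part of genes (split at the median of CpG observed over expected in the first 500 bases of the longest transcript) as for the CpG-poor part. The 95% interval, over 10 strata of expression, was 1.003 to 1.230, and it is too narrow because genes are not independent. Of CpG-rich genes 21.7% were lower and 19.6% higher, and of CpG-poor genes 13.6% and 18.2%. For changes of at least 2-fold, which the test did not name beforehand, the odds ratio was 1.89 (1.48 to 2.41). The rule set beforehand asked for an interval above 1, and its lower end of 1.003 met this barely. Since the interval is too narrow, the test does not decide the question. GC content was not separated from CpG, and genes of the cell-type and p53 lists were not left out, so changes in cell types were not separated either.

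The precursor genes Pax3, Lbx1, Met and Myf5 changed by 2.0 more than the differentiation genes Myog, Actc1, Myl1 and Tnnc1 (exact permutation p = 0.00794, the smallest 5 against 5 can give). These 4 precursor genes are the members of the myogenic list with the smallest p, so the gap follows from their choice and decides nothing about a lower share of mesenchyme, which stays open. In knockout 1 the myogenic score was -1.15.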
